A study of Mus musculus with 8 samples.

How the data were processed

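Tumours were dissociated with trypsin and DNase, passed through a 40 µm strainer and treated with red blood cell lysis solution, and libraries were made with the Chromium Single Cell 3' v3.1 chemistry, per the labels' protocols. The deposited matrices hold raw UMI counts per gene and barcode, made by the authors with Cell Ranger 7.1.0, per the file headers. STAR, Seurat 4.1.1 and the genome build GRCm38 are named in the submitters' processing notes without a role; the annotation release and the settings for calling cells are not given in the sources used here. Each of the 8 matrices held 33954 genes, of which 32218 (94.89%) were found by identifier in GENCODE M21 on GRCm38; 74 genes shared a symbol with another. The counting tags the 3' end of transcripts, so near-identical paralogs and pseudogenes can share reads. Groups and replicate numbers came from the sample titles and the series design. The title of 1 shNC library carries no number, and this library was taken as replicate 1. The 1 that ends the title of a knockdown library was taken as its replicate number but may belong to the gene's name, so replicate 1 names these libraries without tying them to each other. Libraries were compared for duplication by a chi-square statistic of their counts per gene, which lay between 63.0 and 514.8 over all pairs, with 15 to 50 shared barcodes, so no library repeated another.

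Barcodes with at least 200 genes, at least 500 UMIs and at most 20% mitochondrial UMIs were kept, 87353 of 90031. Possible doublets were scored per library against simulated doublets (2 per cell, 60 neighbours), and the highest-scoring share, 0.8% per 1000 barcodes, was removed: 7573 cells (8.67%), leaving 7958 to 12552 cells per library. Counts were scaled to 10000 per cell and logged after adding 1. The 2000 most variable genes, without mitochondrial, ribosomal protein, antigen receptor segment, hemoglobin and sex-linked genes and Selenop, gave 30 principal components, and 20 nearest neighbours gave 45 Leiden clusters at resolution 1 (leidenalg 0.10.2) over all libraries with no batch integration. A cluster was named when at least 3 markers of a class lay at least 4-fold above the median cluster in at least 10% of its cells; clusters with markers of several classes were clustered again at resolution 0.5, and 1918 cells stayed unnamed. The markers were fixed before the data were examined. The naming rule was changed after the first clusters were seen, from a fold over the mean of the other clusters to a fold over the median cluster, and the second clustering of mixed clusters was added then. For sub-clusters of the T cell-like class and of the macrophage-like and monocyte-like classes, the marker fold of 2 was chosen after the data were seen, and a check on markers of the main classes was added after sub-cluster shares were seen. Names rebuilt in this way can differ from the study's own.

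Raw counts were summed per library and class, and sums are given as CPM, counts scaled to a common library total. The 6 largest classes with at least 50 cells in each shNC and shSEPP1 library were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM factors, filterByExpr, the 3 shNC and 3 shSEPP1 libraries, no covariate), with Benjamini-Hochberg adjustment within a class and a threshold of 0.05. Fold changes are shSEPP1 over shNC. Of 35 gene lists fixed before the data were examined, those with at least 5 measured genes were tested with camera (limma 3.58.1, preset correlation 0.01, two-sided), adjusted over all lists and classes. Shares of immune classes were taken over immune cells and of other classes over all kept cells, and were compared by exact two-sided permutation tests, for which the smallest p with 3 against 3 is 0.1. SE and CT, with 1 library each, were not tested: levels have exact Poisson 95% intervals, shares exact Clopper-Pearson 95% intervals (scipy 1.17.1), and genes were taken by the size rule, with at least 50 UMIs over both libraries and log2 ratios of CPM + 10, which understate the change of low genes. List medians were set against 10000 random lists matched on mean expression. A gene was counted as possible free RNA in a class where its mean CPM was under 5% of that in another class. Moving from TMM to the size factors of relative log expression shifted the median of all genes by less than 0.1 (log2) in every class, the largest shift being -0.01 in hepatocyte-like cells.

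The genes named were chosen by a rule fixed before the data were examined. In each class these were Selenop and, among genes past the threshold whose groups did not overlap, the 4 with the largest rise and the 4 with the largest fall at a mean CPM of at least 20. Predicted genes, mitochondrial genes, antigen receptor segments and possible free RNA genes were left out. Selenoproteins past the threshold and up to 4 members with the smallest p of a passing list were added, and for SE and CT the 3 genes with the largest ratio each way. A gene with no symbol that the rule took in monocyte-like cells of CT and SE is not described, and 1 gene that it took in T cell-like cells is not reported here.

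The edgeR step was tested on simulated counts for the same libraries, in which it recovered 94.0% of genes changed 2-fold in neutrophil-like cells, 94.0% in macrophage-like, 59.7% in T cell-like, 89.6% in monocyte-like, 20.9% in hepatocyte-like and 71.6% in B cell-like cells. For the SE and CT size rule, 84.5%, 76.5%, 98.0%, 91.5%, 100% and 100% of genes changed 4-fold were found in the same classes. Alternatives fixed in advance were DESeq2 1.42.0, other size factors, no filter or a filter at a mean CPM of 20, stricter cell filters (500 genes, 1000 UMIs, 10% mitochondrial), possible doublets kept, Leiden resolutions of 0.5 and 2, equal cell numbers, possible free RNA genes left out, a term for the library set, an estimated correlation, fry, edgeR on cell counts, other denominators, no mitochondrial limit, other sub-cluster resolutions, other pseudocounts and UMI minimums, and leaving out each library. Restricting a class to its largest cluster, for the tests and for the correlations of SE and CT with the knockdown, using only the 4 libraries with fewer barcodes, naming sub-clusters by their own markers alone, a mean CPM of at least 50 for the correlations, and other pseudocounts for the SE and CT lists were added after the data were seen. Figures were drawn with matplotlib 3.10.9.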

Results

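Single-cell RNA sequencing was carried out on mouse liver tumours of a hepatocellular carcinoma model driven by activated NRas and by myrAKT, a membrane-bound form of the kinase AKT. The 8 libraries fell into 4 groups. These were a control (CT, n = 1) and selenium supplementation (SE, n = 1), and a negative control short hairpin RNA (shNC, n = 3, replicates 1, 2 and 3) and a knockdown of Selenop (shSEPP1, n = 3, replicates 1, 5 and 6). Selenop, formerly Sepp1, encodes selenoprotein P, a secreted selenium carrier made mainly by hepatocytes. The libraries held between 8882 and 14287 barcodes and between 61918079 and 94068241 unique molecular identifiers (UMIs), with a median of 3377 to 4537 UMIs per barcode. After filtering and removal of possible doublets, 79780 cells remained, and 14 classes were named from marker genes. The neutrophil-like class was the most numerous with 42122 cells, followed by macrophage-like cells with 15133, T cell-like cells with 3849, monocyte-like cells with 3743, hepatocyte-like cells with 2782 and B cell-like cells with 2777. The labels do not say whether libraries of a group came from separate animals, so the p-values measure only the spread between these samples. The replicate 1 libraries of shNC and shSEPP1 held more barcodes (12453 and 14287) than the other 4 libraries (8882 to 10721), and values within those 4 libraries are given beside the counts over all 6.

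The comparison of shSEPP1 with shNC addressed which cells and transcripts of the tumour differ when Selenop is knocked down. Selenop itself, on chromosome 15 from 3268547 to 3280508 on the plus strand (GRCm38, ENSMUSG00000064373, a protein-coding gene), was lower in hepatocyte-like and cholangiocyte-like cells of the shSEPP1 tumours. In hepatocyte-like cells the level was 1021, 1130 and 1059.9 counts scaled to a common library total (CPM) in shNC replicates 1, 2 and 3, and 398, 471 and 296 CPM in shSEPP1 replicates 1, 5 and 6. The mean fell from 1070.1 ± 55.0 to 388 ± 87.9 CPM (SD, n = 3 per group). This was 2.76-fold lower as a ratio of means, and edgeR gave a log2 fold change of -1.67 (SE 0.23, edgeR adjusted p = 0.0162, exact permutation p = 0.1, the smallest possible). Within cluster 14, the largest cluster of the class, the log2 fold change was -3.68 (edgeR adjusted p = 6.4e-05). That cluster held 6107 of 8613 Selenop UMIs of the class in shNC and 329 of 2900 in shSEPP1. Cholangiocyte-like cells (25, 32 and 12 in shNC, 73, 148 and 50 in shSEPP1) held 749 ± 256 and 197 ± 43.9 CPM, 3.79-fold lower. Every shSEPP1 library lay below every shNC library (exact permutation p = 0.1). Whether their hepatocyte content differed was not tested. Macrophage-like cells held 871 ± 88.0 and 927 ± 46.7 CPM (log2 fold change 0.12, edgeR adjusted p = 0.776), and endothelial-like cells 995 ± 244 and 728 ± 294 CPM (exact permutation p = 0.4). Levels in monocyte-like cells were 197 ± 52.8 and 175 ± 27.6 CPM (edgeR adjusted p = 0.849) and in T cell-like cells 47.7 ± 20.4 and 52.9 ± 13.6 CPM (edgeR adjusted p = 0.912). In neutrophil-like cells (23.4 ± 3.93 and 22.2 ± 2.41 CPM, edgeR adjusted p = 0.618) Selenop was low, as it was in B cell-like cells (26.8 ± 7.75 and 20.9 ± 1.25 CPM, edgeR adjusted p = 0.994). In both classes it lay under 5% of the level in another class and is possible free RNA. Over all cells the libraries held 448, 427 and 405 CPM in shNC and 354, 354 and 428 CPM in shSEPP1, so the groups overlapped (exact permutation p = 0.3). The hepatocyte-like call was lost within the 4 libraries with fewer barcodes (log2 fold change -1.65, edgeR adjusted p = 0.237), without shNC replicate 1 (-1.62, 0.0782), without shSEPP1 replicate 1 (-1.68, 0.061) and with possible doublets kept (-1.53, 0.0501).

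**Figure D1:**
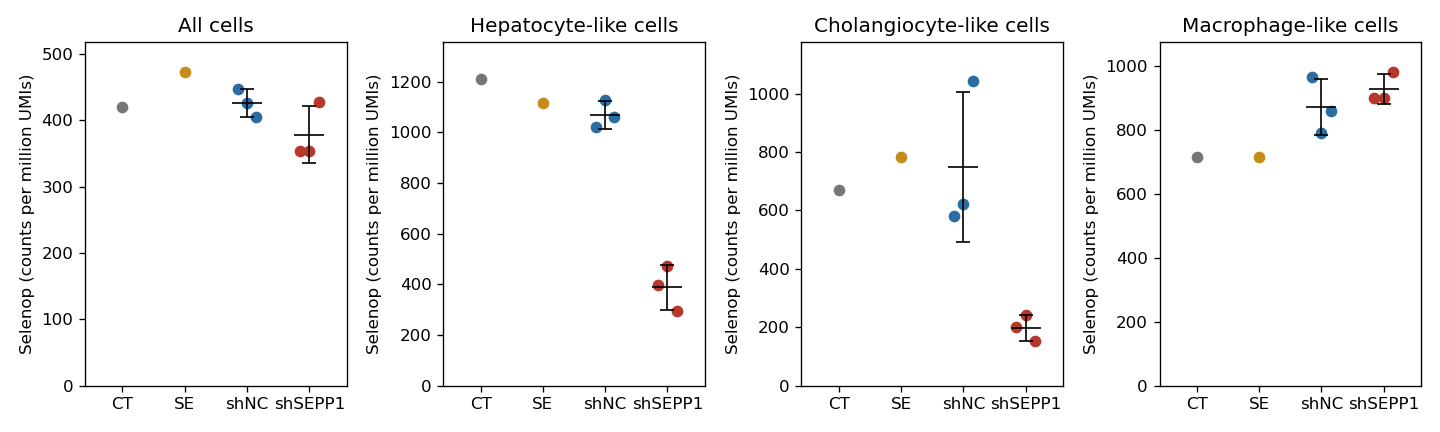
Selenop level in CPM (vertical axes) in each library of the 4 groups (horizontal axes), for all cells and for hepatocyte-like, cholangiocyte-like and macrophage-like cells. Points are libraries, and bars give mean ± SD for shNC and shSEPP1 (n = 3 each). In hepatocyte-like cells the 3 shSEPP1 libraries lay between 296 and 471 CPM, below the 3 shNC libraries at 1021 to 1130 CPM.

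Hepatocyte-like cells of the shSEPP1 tumours expressed more Csmd1, a large membrane protein with complement-control domains, at 129 ± 72.1 CPM against 0.727 ± 0.162 CPM in shNC (SD, n = 3; 872 against 6 UMIs; log2 fold change 7.14, SE 0.59, edgeR adjusted p = 0.000621). Ctnna2, a catenin known from neurons, rose from 2.15 ± 2.70 to 121 ± 89.1 CPM (5.36, SE 0.85, edgeR adjusted p = 0.0211). The insulin-like growth factor binding protein Igfbp2 rose from 1.27 ± 1.16 to 39.2 ± 30.5 CPM (edgeR adjusted p = 0.0162) and the matrix protein Spon1 from 1.86 ± 1.21 to 43.1 ± 29.3 CPM (0.0211). The interferon-induced chemokine Cxcl9 fell from 145 ± 83.7 to 17.8 ± 6.02 CPM (-3.24, SE 0.50, edgeR adjusted p = 0.0187). The cytochrome P450 gene Cyp2a4 fell from 61.8 ± 42.2 to 3.45 ± 5.60 CPM (-4.04, edgeR adjusted p = 0.0463). The pantetheinase gene Vnn3 fell from 178 ± 60.1 to 42.0 ± 15.3 CPM (-2.27, edgeR adjusted p = 0.0187) and the casein gene Csn3 from 35.6 ± 7.43 to 7.62 ± 3.66 CPM (-2.49, 0.0162). Of 9843 genes tested, 87 rose and 25 fell, 13 and 1 of them possible free RNA, and each called gene had all 3 shSEPP1 libraries on one side of all 3 shNC libraries. Groups did not overlap for 21.6% of the tested genes, against 10% by chance. The class was drawn from several clusters: cluster 14 held 460 of 538, 297 of 349 and 203 of 249 cells in shNC, and 142 of 252, 192 of 314 and 278 of 401 cells in shSEPP1. Within cluster 14 there were 1 and 0 UMIs of Csmd1 in shNC and shSEPP1, 1 and 7 of Ctnna2, 5 and 13 of Igfbp2 and 4 and 9 of Spon1, so nearly all of their UMIs in shSEPP1 lay in other clusters of the class. One of these, cluster 21.3, had Csmd1 among its 10 leading genes and raised cholangiocyte markers, and 44.5% of its cells were possible doublets. With these counted it held 3, 2 and 7 cells in shNC and 19, 30 and 11 in shSEPP1. The genes that fell were at -4.41 (Cyp2a4, edgeR adjusted p = 0.0879), -2.70 (Cxcl9, 0.249), -1.49 (Csn3, 0.523) and -1.87 (Vnn3, 0.0703) within cluster 14. The 112 calls became 87 with a term for the library set, 0 within the 4 libraries with fewer barcodes, 2 with possible doublets kept and 2 within the largest cluster. It was 4, 48, 52, 8, 22 and 730 without shNC replicates 1, 2 and 3 and shSEPP1 replicates 1, 5 and 6. All 8 named genes lost their call within the 4 libraries, all but Csmd1 without shNC replicate 1, and all but Csmd1 and Igfbp2 without shSEPP1 replicate 1. Calls were also lost for Cyp2a4, Cxcl9 and Vnn3 without shSEPP1 replicate 5, and Cyp2a4 without shNC replicate 2. With possible doublets kept, Csmd1 was at 2.04 (edgeR adjusted p = 0.305) and Ctnna2 at 1.90 (0.311).

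Among gene lists, the immediate-early and heat shock genes that rise on tissue dissociation were higher in shSEPP1 hepatocyte-like cells. Of 16 measured members 5 rose over all genes tested and 13 adjusted over the list alone (median log2 fold change 1.17, camera adjusted p = 2.0e-13; adjusted p = 0.226 with an estimated correlation). Hspa1a, a heat shock protein, rose from 20.0 ± 10.1 to 159 ± 32.2 CPM (edgeR adjusted p = 0.0114). Its near-identical paralog Hspa1b had 22.4 ± 9.02 and 139 ± 74.2 CPM (0.0255 by edgeR), and reads may be split between the pair. The stress-induced transcription factors Jun and Atf3 rose by 1.70 and 2.12 on the log2 scale (edgeR adjusted p = 0.0304 and 0.0448). The median mitochondrial share over all kept cells was 1.72%, 1.57% and 2.15% in the shNC libraries and 2.07%, 2.92% and 2.88% in the shSEPP1 libraries. In hepatocyte-like cells it was 3.09%, 2.26% and 1.41%, and 3.08%, 2.26% and 1.89%. Barcodes over the mitochondrial limit were 0.827%, 1.27% and 0.788% in shNC and 0.623%, 2.33% and 3.07% in shSEPP1. Genes of the cell cycle were lower, with 0 of 20 past the threshold over all genes and 10 adjusted over the list alone (median -0.87, camera adjusted p = 3.5e-10; adjusted p = 0.31 with an estimated correlation). Lipid synthesis lists were lower too: cholesterol synthesis had a median of -0.63 over 15 genes with 3 lower adjusted over the list alone (camera adjusted p = 2.4e-05; adjusted p = 0.398 with an estimated correlation). Fatty acid synthesis had a median of -0.53 over 15 genes with 2 lower (0.000569; adjusted p = 0.52 with an estimated correlation), among them Acly (-1.27, edgeR adjusted p = 0.0557) and Scd1 (-1.02, 0.0715). Oxidative phosphorylation genes had a median of -0.50 over 18 genes, none called alone (camera adjusted p = 2.5e-05; adjusted p = 0.567 with an estimated correlation). Abundant hepatocyte transcripts, which mark free RNA in other classes, were also lower here, with a median of -0.57 over 15 genes (camera adjusted p = 0.000379; adjusted p = 0.445 with an estimated correlation).

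Neutrophil-like cells of the shSEPP1 tumours expressed less of the interferon-induced genes and more Camp, Ngp, Chil3 and Ltf. Rsad2, an antiviral enzyme, fell from 142 ± 62.2 to 35.1 ± 5.64 CPM (SD, n = 3; log2 fold change -2.08, SE 0.26, edgeR adjusted p = 0.0144). Ifit1, another antiviral gene, fell from 53.1 ± 33.7 to 13.4 ± 3.29 CPM (-2.04, SE 0.37, edgeR adjusted p = 0.0276). The guanylate-binding protein gene Gbp5 fell from 48.4 ± 29.5 to 9.52 ± 1.49 CPM (-2.43, SE 0.45, edgeR adjusted p = 0.028). Nlrc5, the transactivator of MHC class I genes, fell from 39.7 ± 14.5 to 9.18 ± 2.92 CPM (-2.18, SE 0.32, 0.0162). Camp, the cathelicidin of neutrophil granules, rose from 20.0 ± 13.9 to 407 ± 339 CPM (4.29, SE 0.79, edgeR adjusted p = 0.0281). Ngp, another granule protein, rose from 46.1 ± 17.1 to 539.6 ± 305 CPM (3.48, SE 0.47, 0.0146). The chitinase-like gene Chil3 rose from 24.7 ± 4.68 to 308 ± 137 CPM (3.57, SE 0.37, edgeR adjusted p = 0.012). Lactotransferrin, Ltf, rose from 38.2 ± 5.03 to 179 ± 110 CPM (2.17, SE 0.41, 0.0319). The list of neutrophil granule and activation genes did not pass the test in this class, with 3 of 16 higher and 1 lower over all genes and 5 and 3 adjusted over the list alone (median 0.33, camera adjusted p = 0.0678; adjusted p = 0.653 with an estimated correlation). It passed without shNC replicate 3 (camera adjusted p = 0.00378), shSEPP1 replicate 5 (0.0413) or shSEPP1 replicate 6 (5.6e-05). The class lay in different clusters by group. With possible doublets counted, cluster 8, with Retnlg and Ngp among its leading genes, held 231, 77 and 160 cells in shNC and 1089, 890 and 579 in shSEPP1. Cluster 11, with Slfn4, Rsad2 and Ifit1 among its leading genes, held 620, 271 and 509 cells in shNC and 182, 70 and 123 in shSEPP1. Of 13238 genes, 117 rose and 274 fell, all without overlap between the groups, and 42 and 21 of them were possible free RNA. The groups did not overlap for 25.5% of the tested genes, against 10% by chance. The median mitochondrial share of neutrophil-like cells did not overlap either. It was 1.03%, 0.60% and 0.65% in the shNC libraries and 1.51%, 1.79% and 1.90% in the shSEPP1 libraries. The 391 calls became 1100 with a term for the library set, 128 within the 4 libraries with fewer barcodes. It was 517, 84, 150, 131, 0 and 284 without shNC replicates 1, 2 and 3 and shSEPP1 replicates 1, 5 and 6. Without shSEPP1 replicate 5, 1634 genes had an unadjusted p under 0.05 by edgeR. Besides all 8 named genes without shSEPP1 replicate 5, calls were lost for Camp, Ngp, Ltf and Gbp5 without shNC replicate 2, for Camp, Ltf and Gbp5 without shNC replicate 3, and for Ltf without shNC replicate 1. They were also lost for Ltf, Gbp5 and Ifit1 without shSEPP1 replicate 1, for Gbp5 and Ifit1 without shSEPP1 replicate 6, and for Camp, Ngp and Ltf within the 4 libraries. In the largest cluster alone Ltf was at -0.13 (edgeR adjusted p = 0.843), Gbp5 at -1.72 (0.301) and Ifit1 at 0.03 (0.973).

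**Figure D2:**
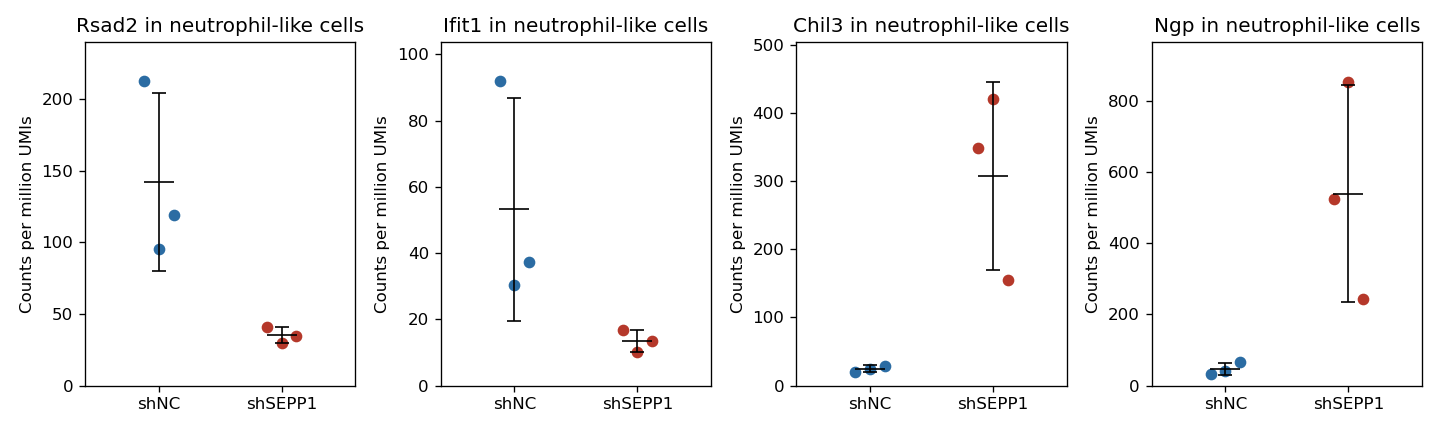
Level in CPM (vertical axes) of Rsad2, Ifit1, Chil3 and Ngp in neutrophil-like cells of each library, by group (horizontal axes). Points are libraries, and bars give mean ± SD for shNC and shSEPP1 (n = 3 each). Rsad2 averaged 142 CPM in shNC and 35.1 CPM in shSEPP1, and Chil3 24.7 and 308 CPM, with no overlap between the groups.

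The interferon response list fell in neutrophil-like cells as a group, with 14 of 22 members lower over all genes tested and 21 adjusted over the list alone (median log2 fold change -1.60, camera adjusted p = 5.4e-32; adjusted p = 0.131 with an estimated correlation). Its member Isg15, a ubiquitin-like modifier, fell from 547 ± 98.0 to 186 ± 10.3 CPM (edgeR adjusted p = 0.012). The chemokine gene Cxcl10 fell from 213 ± 20.8 to 71.6 ± 18.3 CPM (edgeR adjusted p = 0.014) and Irf7, a transcription factor of the interferon response, from 52.4 ± 22.3 to 18.5 ± 0.863 CPM (0.0212). Genes of MHC class I presentation fell with it, 7 of 13 over all genes and 12 adjusted over the list alone (median -0.72, camera adjusted p = 1.7e-15; adjusted p = 0.239 with an estimated correlation). Among them was B2m, the invariant light chain, at 1212 ± 163 and 715 ± 112 CPM (edgeR adjusted p = 0.0351). Interferon genes were also lower in monocyte-like cells (22 genes, median -0.89, 0 called over all genes and 17 adjusted over the list alone, camera adjusted p = 6.6e-18; adjusted p = 0.302 with an estimated correlation). In macrophage-like cells the median was -0.65 over 23 genes, with 0 and 7 called (1.7e-13; adjusted p = 0.332 with an estimated correlation). In hepatocyte-like cells it was -0.61 over 18 genes, with 1 and 3 called (0.000284; adjusted p = 0.332 with an estimated correlation). In B cell-like cells it was -0.27 over 11 genes with none called (0.0115; adjusted p = 0.302 with an estimated correlation). That result was lost without shNC replicate 1 (camera adjusted p = 0.105), shNC replicate 3 or shSEPP1 replicate 1. The MHC class I list was lower in monocyte-like cells (median -0.58, 11 of 13 adjusted over the list alone), macrophage-like cells (-0.42, 7 of 13), hepatocyte-like cells (-0.46, 0 of 13) and B cell-like cells (-0.30, 0 of 13). Camera adjusted p were 5.3e-12, 2.2e-08, 0.0324 and 6.2e-05, and adjusted p were 0.302, 0.31, 0.638 and 0.175 with an estimated correlation. In T cell-like cells neither list passed, with medians of -0.07 for interferon genes (camera adjusted p = 0.382) and -0.02 for MHC class I genes (0.314). There the interferon median was 0.33 without shNC replicate 1 (camera adjusted p = 0.0305) and -0.37 without shNC replicate 3 (1.4e-06). Whether the changes differed between classes was not tested.

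Among the selenoproteins, Txnrd1, the cytosolic thioredoxin reductase, fell in neutrophil-like cells from 459 ± 15.1 to 296 ± 21.5 CPM (log2 fold change -0.70, SE 0.12, edgeR adjusted p = 0.0233). The call was lost without any 1 library except shNC replicate 1 and within the 4 libraries with fewer barcodes. The selenoprotein list, tested for a shift one way against other genes, passed in none of the 6 classes over all 6 libraries. Fry's mixed test asks whether the members change in either direction and does not compare them with other genes. It passed in neutrophil-like (fry mixed adjusted p = 0.000599), hepatocyte-like (0.00733, Selenop itself being a member) and monocyte-like cells (0.0258), and not in macrophage-like (0.0586), T cell-like (0.563) and B cell-like cells (0.461). In hepatocyte-like cells its median was -0.24 over 20 genes (camera adjusted p = 0.075), and it passed without shNC replicate 2 (-0.16, 0.0104) and with possible free RNA genes left out (-0.26, 0.0169). In neutrophil-like cells its median was -0.04 and its mean 0.04 over 19 genes, and the test gave the direction of the median (camera adjusted p = 0.871). NRF2 antioxidant genes had a median of -0.32 in neutrophil-like cells (15 genes, camera adjusted p = 0.0433; adjusted p = 0.582 with an estimated correlation). There the cystine transporter gene Slc7a11 fell from 1876 ± 54.3 to 1169 ± 27.4 CPM (edgeR adjusted p = 0.0233). The same list had a median of -0.35 in hepatocyte-like cells (0.0209; adjusted p = 0.653 with an estimated correlation) and 0.28 in monocyte-like cells (0.0046; adjusted p = 0.284 with an estimated correlation).

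Macrophage-like cells of the shSEPP1 tumours expressed more of the genes typical of resident liver macrophages. The folate receptor gene Folr2 rose from 17.2 ± 2.42 to 52.1 ± 6.80 CPM (SD, n = 3; log2 fold change 1.63, SE 0.15, edgeR adjusted p = 0.0215). The eotaxin gene Ccl24 rose from 36.4 ± 12.6 to 129 ± 11.1 CPM (1.86, SE 0.22, edgeR adjusted p = 0.0391). The sialyltransferase gene St3gal5 rose from 17.7 ± 2.08 to 50.0 ± 4.24 CPM (1.53, SE 0.13, edgeR adjusted p = 0.0215). The fatty acid binding protein gene Fabp7 rose from 11.2 ± 3.68 to 44.6 ± 12 CPM (2.02, SE 0.28, edgeR adjusted p = 0.04995). Asb2, a subunit of a ubiquitin ligase, fell from 46.7 ± 0.715 to 15.7 ± 4.39 CPM (-1.54, SE 0.18, 0.0391). Of 11 Kupffer cell identity genes 3 rose over all genes, and 8 were higher and 2 lower adjusted over the list alone (median 1.36, mean 0.84, camera adjusted p = 1.5e-13; adjusted p = 0.131 with an estimated correlation). Vsig4, a complement receptor, rose from 46.5 ± 6.07 to 131 ± 20.6 CPM (edgeR adjusted p = 0.0304) and Cd5l, a scavenger receptor family protein, from 93.5 ± 12.2 to 257 ± 47.9 CPM (0.0391). Genes of alternatively activated and tumour macrophages rose as a group, 2 of 17 over all genes and 9 adjusted over the list alone (median 0.73, camera adjusted p = 3.6e-16; adjusted p = 0.131 with an estimated correlation). The secreted phosphoprotein gene Spp1 had 513 ± 44.7 and 1734 ± 596 CPM (edgeR adjusted p = 0.0545). Cell cycle genes fell as a group, 18 of 20 adjusted over the list alone and 0 over all genes (median -0.75, camera adjusted p = 1.4e-16; adjusted p = 0.316 with an estimated correlation). Of 14003 genes, 24 rose, 8 of them possible free RNA, and 4 fell, none of them possible free RNA. The groups did not overlap for 18.8% of the tested genes, against 10% by chance. Median UMIs per macrophage-like cell were 11957, 13628.5 and 12109.5 in shNC and 8084.5, 9160 and 9757.5 in shSEPP1. The class lay in different clusters by group. With possible doublets counted, cluster 13, with a median of 1247 UMIs per cell, held 286, 68 and 105 cells in shNC and 767, 456 and 459 in shSEPP1. Cluster 10, with a median of 13994 UMIs, held 191, 285 and 558 cells in shNC and 63, 93 and 170 in shSEPP1. The 28 calls became 437 with a term for the library set, 33 within the 4 libraries with fewer barcodes, 437 by DESeq2, and 8 in the largest cluster alone. It was 101, 0, 1, 0, 0 and 130 without shNC replicates 1, 2 and 3 and shSEPP1 replicates 1, 5 and 6. All 5 named genes lost their call without shNC replicate 2, shSEPP1 replicate 1 or shSEPP1 replicate 5, all but Ccl24 without shNC replicate 3, and Fabp7 without shSEPP1 replicate 6. In the largest cluster Ccl24 was at 0.03 (edgeR adjusted p = 0.984), Folr2 at 0.79 (0.19), St3gal5 at 0.92 (0.386) and Asb2 at -0.88 (0.178).

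Monocyte-like cells of the shSEPP1 tumours expressed less Cxcl16, a chemokine and scavenger receptor, at 90.5 ± 9.72 CPM against 229 ± 6.70 CPM in shNC (SD, n = 3; log2 fold change -1.38, SE 0.13, edgeR adjusted p = 0.00902). The costimulatory receptor Cd40 fell from 50.1 ± 13 to 15.6 ± 2.31 CPM (-1.72, SE 0.23, edgeR adjusted p = 0.0421). The lectin Cd72 fell from 31.5 ± 6.02 to 8.79 ± 2.02 CPM (-1.81, SE 0.22, 0.0234) and the integrin Itga9 from 94.7 ± 9.16 to 34.6 ± 7.24 CPM (-1.51, SE 0.18, 0.0234 by edgeR). The transcription factor Klf9 rose from 28.2 ± 4.91 to 65.0 ± 8.52 CPM (1.15, SE 0.16, 0.0421). MHC class II genes fell as a group, with 0 of 8 called over all genes and 7 adjusted over the list alone (median -1.15, camera adjusted p = 1.9e-13; adjusted p = 0.302 with an estimated correlation). H2-Ab1, a class II chain, had 3426 ± 225 CPM in shNC and 1419 ± 553 CPM in shSEPP1 (edgeR adjusted p = 0.0738). Glycolysis and hypoxia genes rose as a group, 11 of 17 adjusted over the list alone and 0 over all genes (median 0.41, camera adjusted p = 5.3e-12; adjusted p = 0.131 with an estimated correlation). Genes of alternatively activated macrophages had a median of 0.38 over 14 genes, with 6 higher and 1 lower adjusted over the list alone (0.0046; adjusted p = 0.284 with an estimated correlation). Chil3 had 442 ± 99.6 and 1970 ± 1128 CPM (edgeR adjusted p = 0.0787). Kupffer cell identity genes, higher in macrophage-like cells, had a median of -0.75 over 5 genes here (0.0179; adjusted p = 0.393 with an estimated correlation). This was lost without shNC replicate 3 (camera adjusted p = 0.208) or shSEPP1 replicate 1. Cholesterol synthesis genes had a median of -0.45 over 12 genes, with 5 lower adjusted over the list alone (1.4e-06; adjusted p = 0.284 with an estimated correlation). Of 9838 genes, 1 rose and 5 fell, 0 of them possible free RNA, with 4 higher and 9 lower under the size factors of relative log expression. The groups of libraries did not overlap for 15.2% of the tested genes, against 10% by chance. The 6 calls became 323 with a term for the library set, 245 within the 4 libraries with fewer barcodes, 134 by DESeq2, and 0 at a Leiden resolution of 2. At resolution 1 edgeR gave 994 genes with an unadjusted p under 0.05. The count was 116, 0, 0, 25, 0 and 86 without shNC replicates 1, 2 and 3 and shSEPP1 replicates 1, 5 and 6. All 5 named genes lost their call without shNC replicate 2, shNC replicate 3 or shSEPP1 replicate 5 and at that resolution.

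T cell-like and B cell-like cells had 0 genes past the threshold by edgeR. In T cell-like cells 720 of 10089 genes had an unadjusted p under 0.05 and DESeq2 called 4, and the groups did not overlap for 11.3% of the genes. In B cell-like cells 415 of 7887 did, DESeq2 called 5, and the groups did not overlap for 10.5%, against 10% by chance. With a term for the library set the counts were 0 and 31, and within the 4 libraries with fewer barcodes 13 and 6. Leaving out libraries gave 86 genes in T cell-like cells without shNC replicate 1 and 1 without shNC replicate 3, and 8, 2 and 7 in B cell-like cells without shSEPP1 replicates 1, 5 and 6. As a group, cell cycle genes were lower in T cell-like cells, 7 of 20 adjusted over the list alone (median -0.87, camera adjusted p = 3.7e-13; adjusted p = 0.401 with an estimated correlation). The groups did not overlap for 2 of the 20, against 10% by chance. Cluster 35, a T cell-like cluster, held 1655 of 3938, 4912 of 6557 and 22432 of 27698 UMIs of these genes in shNC, and 1794 of 4212, 883 of 2112 and 1755 of 2785 in shSEPP1. It had 10, 28 and 121 cells in shNC and 12, 8 and 10 in shSEPP1, so that shNC replicate 3 stood apart and shNC replicate 1 did not. For the cell cycle in T cell-like cells the median was -0.48 without shNC replicate 3 (camera adjusted p = 3.4e-07) and -0.57 with possible doublets kept (3.6e-08). The ribonucleotide reductase gene Rrm2 had 43.8 ± 23.1 CPM in shNC and 13.7 ± 3.43 CPM in shSEPP1 (SD, n = 3; edgeR adjusted p = 0.612). Genes of the unfolded protein response rose as a group in B cell-like cells, 6 of 11 adjusted over the list alone (median 0.46, camera adjusted p = 6.0e-10; adjusted p = 0.302 with an estimated correlation). Xbp1, a transcription factor of that response and of antibody secretion, had 49.4 ± 16.8 and 115 ± 30.7 CPM (edgeR adjusted p = 0.175).

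Extracellular matrix genes were higher in shSEPP1 in all 6 tested classes. The median log2 fold change was 1.53 in neutrophil-like cells (14 genes, 8 up over all genes and 12 adjusted over the list alone), 1.55 in macrophage-like cells (14 genes, 3 and 12), and 1.42 in T cell-like cells (7 genes, 0 and 6). It was 1.19 in monocyte-like cells (9 genes, 0 and 8), 0.66 in hepatocyte-like cells (8 genes, 2 and 4) and 1.55 in B cell-like cells (5 genes, 0 and 5). Camera adjusted p were 1.5e-23, 8.2e-30, 1.3e-22, 1.5e-16, 0.0132 and 3.8e-20, and adjusted p were 0.131, 0.0705, 0.131, 0.0705, 0.302 and 0.0705 with an estimated correlation. The hepatocyte-like result was lost without shNC replicate 2 (camera adjusted p = 0.119). Levels were low: in neutrophil-like cells the collagen genes Col1a1 and Col3a1 had 8.02 ± 1.29 and 10.7 ± 1.71 CPM in shNC and 23.9 ± 1.29 and 38.8 ± 7.09 CPM in shSEPP1 (edgeR adjusted p = 0.012 for both). Of the members, 13 of 14 in neutrophil-like, 12 of 14 in macrophage-like, and 7 of 7 in T cell-like cells were possible free RNA, with a mean CPM under 5% of that in another class. So were 7 of 9 in monocyte-like, 7 of 8 in hepatocyte-like and 5 of 5 in B cell-like cells. Stellate/fibroblast-like cells made up 0.768% ± 0.122 of kept cells in shNC and 1.93% ± 0.513 in shSEPP1.

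Other transcripts that can mark free RNA differed between libraries, by group in some classes and not in others. Transcripts of red blood cells, which the preparation lysed, summed to 301 ± 261 CPM in neutrophil-like cells of shNC and 2201 ± 1581 CPM of shSEPP1, and to 279 ± 260 and 1612 ± 1008 CPM in macrophage-like cells. In monocyte-like cells they were 36.0 ± 11.8 and 537 ± 559 CPM, and in B cell-like cells 31.1 ± 9.72 and 3315 ± 5441 CPM. Each shSEPP1 library lay above each shNC library in macrophage-like (642 to 2654 against 22.5 to 542 CPM), monocyte-like (149.9 to 1178 against 22.9 to 45.8 CPM) and B cell-like cells (161 to 9598 against 24.3 to 42.2 CPM). The neutrophil sums overlapped, at 233, 80.6 and 589 CPM in shNC and 3721, 2319 and 564 CPM in shSEPP1. In T cell-like cells they were 987 ± 1656 and 580.2 ± 713 CPM and in hepatocyte-like cells 988 ± 1641 and 2671 ± 2259 CPM, also overlapping. As lists those of neutrophil-like and macrophage-like cells had medians of 2.83 (5 genes, 5 higher adjusted over the list alone) and 2.61 (4 higher), with camera adjusted p of 8.5e-05 and 7.3e-05, and adjusted p of 0.402 and 0.401 with an estimated correlation. Hepatocyte transcripts summed to 662 ± 194 and 495 ± 124 CPM in neutrophil-like cells, 905 ± 109 and 1058 ± 105 CPM in macrophage-like cells and 526 ± 154 and 623 ± 39.3 CPM in monocyte-like cells, with overlap in each. They also overlapped in B cell-like cells, at 506 ± 276 and 329 ± 194 CPM, and in T cell-like cells they were lower in each shSEPP1 library, at 399 ± 52.0 and 310 ± 41.1 CPM. Their list had medians of -0.71 in neutrophil-like, -0.50 in T cell-like and -0.55 in B cell-like cells (camera adjusted p = 0.00782, 0.000125 and 0.000984; adjusted p = 0.673, 0.316 and 0.638 with an estimated correlation). The neutrophil result was lost without shNC replicate 1 (camera adjusted p = 0.0594), shNC replicate 2 or shSEPP1 replicate 1. Neutrophil granule genes were higher in macrophage-like cells (median 0.69 over 17 genes, 12 of them possible free RNA, camera adjusted p = 1.7e-05; adjusted p = 0.226 with an estimated correlation). Without those genes the median was -0.04 (camera adjusted p = 0.734). Across the 6 classes 61 of 181 lists tested passed with the preset correlation and 0 with an estimated one, where the smallest adjusted p was 0.0705. With the preset correlation, other splits of the 6 libraries passed 24 to 60 lists. By fry, which asks whether a list moves one way on balance, 3 passed, all of them the matrix list, in neutrophil-like (fry adjusted p = 0.0422), macrophage-like (0.00991) and monocyte-like cells (0.011). By its mixed form, which asks whether members change in either direction, 64 of the 181 passed.

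Stromal, bile duct and red blood cell classes took larger shares of the shSEPP1 tumours, and dendritic cells smaller ones. Cholangiocyte-like cells made up 0.255% ± 0.135 of kept cells in shNC and 0.911% ± 0.614 in shSEPP1 (SD, n = 3, 3.57-fold), and stellate/fibroblast-like cells 0.768% ± 0.122 and 1.93% ± 0.513 (2.51-fold). Endothelial-like cells made up 1.90% ± 0.617 and 2.76% ± 0.210 (1.45-fold) and erythroid-like cells, left after red blood cell lysis, 0.110% ± 0.0503 and 0.719% ± 0.252 (6.51-fold). Of immune cells, conventional dendritic cell-like cells were 4.95% ± 1.34 and 2.73% ± 0.380, plasmacytoid dendritic cell-like cells 0.482% ± 0.252 and 0.186% ± 0.0143, and the cells of cluster 42 0.114% ± 0.0143 and 0.201% ± 0.0507. Cluster 42 met the rule for mast/basophil-like cells, but its leading genes Ctsg, Elane, Prtn3 and Mpo are those of granulocyte progenitors, so that name is uncertain. For these 7 of 14 classes the groups did not overlap (exact two-sided permutation p = 0.1 each, the smallest possible, adjusted p = 0.2). Macrophage-like cells were 18.4% ± 1.14 and 22.5% ± 2.79 of immune cells (exact permutation p = 0.2), and T cell-like cells 6.57% ± 4.41 and 3.96% ± 1.33 (p = 0.6 by the same permutation test). NK/ILC-like cells were 0.704% ± 0.198 and 0.364% ± 0.126 (permutation p = 0.2) and B cell-like cells 3.08% ± 0.717 and 4.15% ± 1.49 (permutation p = 0.4). Monocyte-like cells were 4.40% ± 1.39 and 5.07% ± 1.57 (permutation p = 0.6) and neutrophil-like cells 61.3% ± 7.77 and 60.8% ± 2.26 (permutation p = 1). Hepatocyte-like cells were 4.03% ± 1.04 and 3.24% ± 1.14 of kept cells (permutation p = 0.4). An edgeR test on cell counts gave adjusted p = 0.000441 for erythroid-like, 0.00579 for cholangiocyte-like, 0.0294 for stellate/fibroblast-like, 0.0294 for plasmacytoid and 0.0377 for conventional dendritic cell-like cells. It gave 0.283 for endothelial-like and 0.0627 for cluster 42. All shares are of cells that survived trypsin digestion and a 40 µm strainer.

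**Figure D3:**
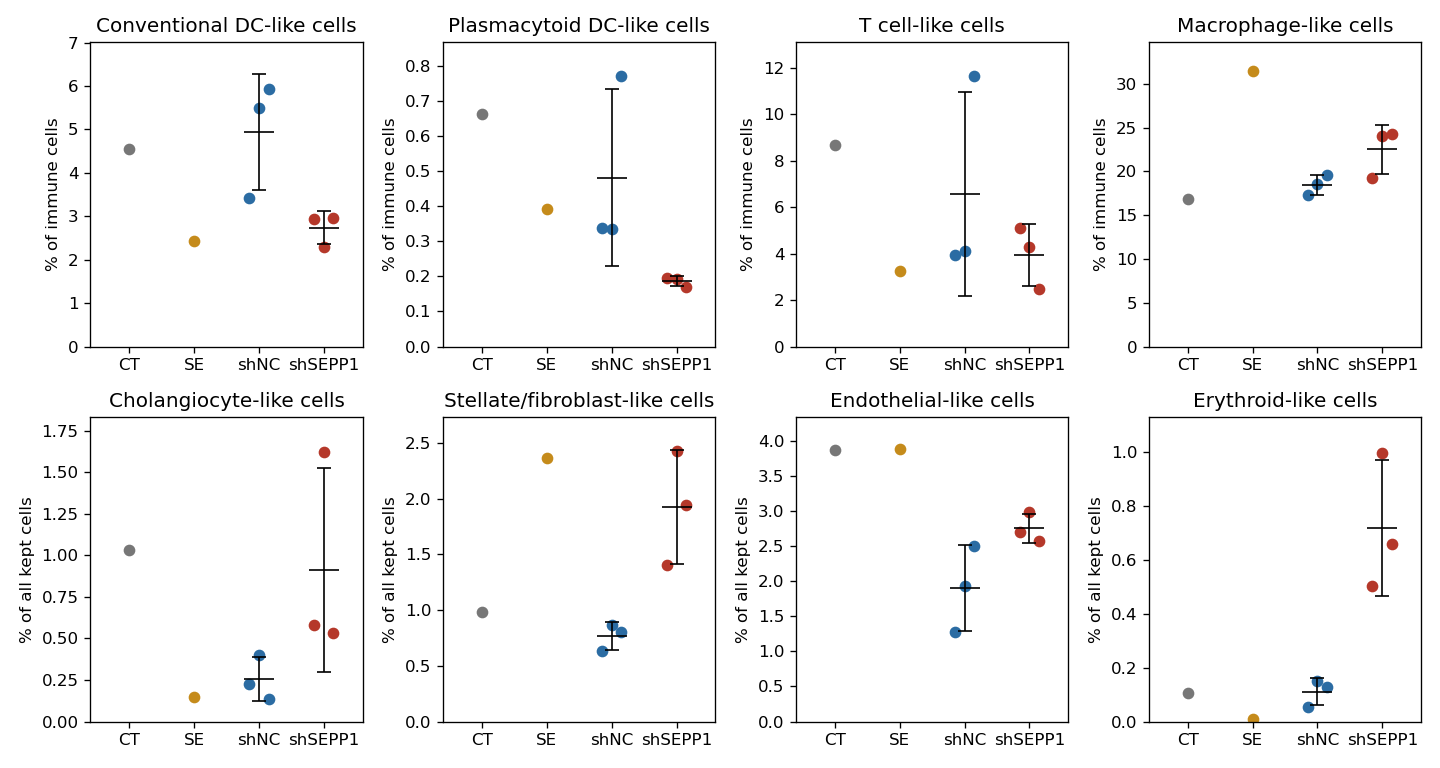
Share of each library's cells in 8 classes, in percent of immune cells (dendritic, T cell-like and macrophage-like) or of all kept cells (the others), by group. Points are libraries, and bars give mean ± SD for shNC and shSEPP1 (n = 3 each). Erythroid-like cells averaged 0.110% in shNC and 0.719% in shSEPP1, and conventional dendritic cell-like cells 4.95% and 2.73%, with no overlap between the groups.

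Within the macrophage-like and monocyte-like cells, the Kupffer-like subclass took 2.38% ± 0.430 in shNC and 5.09% ± 0.823 in shSEPP1 (SD, n = 3), with no overlap between the groups (exact permutation p = 0.1, adjusted p = 0.4). Its markers are in the Kupffer cell identity list, so share and list are not independent. Regulatory T-like cells were 7.85% ± 1.86 and 11.9% ± 1.16 of T cell-like cells, also without overlap (exact permutation p = 0.1, adjusted p = 0.4). CD8, CD4, naive and gamma-delta/IL17 T-like cells were 13.9% ± 5.26, 21.7% ± 9.92, 8.76% ± 2.25 and 7.97% ± 4.09 in shNC. In shSEPP1 they were 29.3% ± 19.1, 15.6% ± 6.36, 12.9% ± 5.48 and 8.50% ± 4.11 (permutation p = 0.2, 0.6, 0.4 and 0.8). Unnamed sub-clusters held 39.8% ± 3.26 and 21.8% ± 8.80 of T cell-like cells, without overlap (permutation p = 0.1). Those of 219, 151 and 41 cells raised 6, 5 and 4 of 6 CD8 markers, so the CD8 share leaves these out. Lipid-associated macrophage-like cells were 19.1% ± 6.82 and 24.0% ± 1.48 (permutation p = 0.4). Monocyte-derived ones were 41.0% ± 1.88 and 34.1% ± 7.46 (permutation p = 0.3). Unnamed macrophage-like and monocyte-like cells were 37.5% ± 8.96 and 36.8% ± 8.74.

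The SE and CT libraries set a tumour with selenium supplementation beside a control. With 1 library each there was no replicate check and no test. The values compare these 2 libraries and not the conditions, and the 95% intervals cover counting error only. Macrophage-like cells were 31.4% (exact Clopper-Pearson interval 30.5 to 32.4) of immune cells in SE and 16.8% (16.1 to 17.6) in CT. T cell-like cells were 3.27% (2.91 to 3.65) in SE and 8.67% (8.11 to 9.26) in CT, and monocyte-like cells 4.61% (4.19 to 5.05) and 8.14% (7.60 to 8.72). Conventional dendritic cell-like cells were 2.43% (2.12 to 2.76) and 4.55% (4.13 to 4.99), and neutrophil-like cells 52.6% (51.5 to 53.6) and 56.0% (55.0 to 57.0). Of all kept cells, hepatocyte-like cells were 4.69% (4.30 to 5.11) in SE and 1.74% (1.49 to 2.01) in CT, stellate/fibroblast-like cells 2.37% (2.09 to 2.68) and 0.985% (0.803 to 1.20), and cholangiocyte-like cells 0.15% (0.0857 to 0.243) and 1.03% (0.847 to 1.25). Endothelial-like cells, at 3.89% and 3.88%, and B cell-like cells, at 4.40% and 4.25%, had overlapping intervals. Selenop in hepatocyte-like cells was at 1116 CPM (exact Poisson interval 1089.9 to 1143) in SE and 1210 (1159 to 1262) in CT, and in endothelial-like cells at 482 (466 to 499) and 1174 (1149 to 1200).

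Macrophage-like cells of the SE library held more arginase transcript, Arg1, at 841 CPM (exact Poisson interval 831 to 852) against 7.11 (6.01 to 8.35) in CT. They held more of the acute-phase gene Saa3, at 531 (522 to 539) against 5.33 (4.39 to 6.42), and more fibronectin transcript, Fn1, at 1248 (1236 to 1261) against 119 (114 to 123). Cluster 19 of this class, led by Arg1, Saa3 and F13a1, with Fn1 among its 10 leading genes, held 1106 cells in SE and 10 in CT, possible doublets counted. Lower were the Kupffer cell lectin Clec4f, at 4.02 CPM (3.34 to 4.81) against 176 (170.2 to 182), and Cd5l, at 43.9 (41.5 to 46.3) against 307 (299 to 314). The complement gene C6 was at 0.201 (0.0738 to 0.438) against 42.6 (39.9 to 45.5). Of the 11 Kupffer cell identity genes 8 were lower by the size rule, and the list's median log2 ratio of -1.64 lay at percentile 0 of 10000 random lists of the same size and expression. Most lists measured in this class, and many in the other classes, lay in the outer 5% of their random lists. A percentile near 0 or 100 therefore does not single out a list. The Kupffer-like subclass was 0.272% (0.124 to 0.515) of macrophage-like and monocyte-like cells in SE and 5.70% (4.79 to 6.71) in CT. Glycolysis and hypoxia genes had a median of 0.69 over 17 genes (percentile 100, 3 higher). Acute-phase genes had a median of 0.99 (percentile 100, 7 higher), beside 1.30 (percentile 100, 10 higher) for the abundant hepatocyte transcripts that mark free RNA. The acute-phase members Fga, Fgb, Fgg, Hpx, Orm1 and Orm2, all higher by the size rule, were possible free RNA in this class. Lower medians were found for interferon response genes (-0.62, percentile 0), MHC class II genes (-0.60, percentile 0) and chemokines (-0.67, percentile 0, 2 higher and 4 lower). The size rule took genes with a log2 ratio of CPM + 10 of at least 1 and beyond every ratio within shNC and within shSEPP1. By it 90 genes were higher and 36 lower of 13253 compared, 41 of them possible free RNA. With TMM factors these were 62 and 46.

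T cell-like cells of the SE library held more of the naive and memory genes and less of the checkpoint genes. All 10 naive and memory genes had a ratio above 0, with a median of 0.72 (percentile 100, 2 higher by the size rule). The exhaustion and checkpoint list had a median of -0.93 over 14 genes (percentile 0, 5 lower), including Rgs16, a regulator of G protein signalling, at 24.1 (17.1 to 32.9) against 122 (112 to 133). Regulatory T cell genes had a median of -0.65 (percentile 0, 3 lower) and cytotoxic effector genes -0.35 (percentile 0.01, 3 lower). Naive T-like cells were 29.0% (23.9 to 34.5) of T cell-like cells in SE and 9.26% (7.35 to 11.5) in CT. CD4 T-like cells were 11.3% (7.98 to 15.5) and 37.5% (34.2 to 41.0), and regulatory T-like cells 5.33% (3.08 to 8.52) and 12.6% (10.4 to 15.1). Other genes named by size were Taf4b (148 against 58.4 CPM) and Rras2 (249.6 against 103 CPM), higher in SE. Lower were Penk, the enkephalin precursor (11.1 against 81.8 CPM), and Ier5l (26.6 against 149 CPM). By the size rule 51 genes were higher and 57 lower of 8792, 36 of them possible free RNA.

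Hepatocyte-like cells differed at 47 genes higher and 420 lower in SE of 8519 compared by the size rule, 89 of them possible free RNA, and with TMM factors at 176 higher and 166 lower. Higher were Cxcl9 at 166 CPM (156 to 176) against 24.4 (17.7 to 32.9) and tyrosine aminotransferase, Tat, at 163 (153 to 173) against 25.0 (18.1 to 33.5). Arg1 was at 614 (595 to 634) against 155 (138 to 175). Lower were the cytochrome P450 gene Cyp2e1 at 13 (10.3 to 16.2) against 195 (175 to 216) and the chemokine gene Cxcl5 at 3.21 (1.964 to 4.965) against 70.9 (59.0 to 84.5). The bile acid and drug transporter gene Slco1b2 was at 1.93 (0.997 to 3.37) against 61.3 (50.3 to 74.0). Genes of differentiated hepatocyte function had a median of 0.58 (percentile 100), glycolysis genes 0.45 (percentile 100) and oxidative phosphorylation genes 0.37 (percentile 98.97). Dissociation stress genes had -0.96 (percentile 0, 3 lower), MHC class II genes -1.03 (percentile 0.04) and oncofetal genes -0.72 (percentile 0.06). Cluster 14 held 436 of 501 hepatocyte-like cells in SE and 81 of 178 in CT. The median hepatocyte-like cell had 5885 UMIs and 1579 genes in SE, and 2650.5 UMIs and 925 genes in CT.

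In neutrophil-like cells of the SE library the stefin gene Stfa2 was at 1.48 CPM (0.941 to 2.23) against 33.7 (31.1 to 36.4) in CT, and the related Cstdc5 at 4.26 (3.29 to 5.42) against 37.5 (34.8 to 40.3). Retnlg, a resistin-like protein of neutrophils, was at 513 (502 to 524) against 1675 (1656 to 1693). No gene was named as higher after the exclusions. By the size rule 34 were higher and 14 lower of 12153 (31 and 24 with TMM factors), 37 of them possible free RNA. Hepatocyte transcripts summed to 2583 CPM in neutrophil-like cells of SE and 668 CPM of CT, 3.87-fold more, and their list had a median of 1.69 (percentile 100, 12 higher). Interferon response genes had a median of -0.20 and MHC class II genes -0.42 (percentile 0 for both). Monocyte-like cells held less Ccl2, a monocyte chemoattractant, at 100.2 CPM (90.1 to 111) against 274 (263 to 287), and less Ccl12, at 7.47 (4.92 to 10.9) against 44.5 (39.8 to 49.6). The chemokine list had a median of -0.65 (percentile 0, 4 lower). Arg1 was at 39.0 (32.8 to 46.0) against 5.11 (3.61 to 7.01) and the lectin gene Mgl2 at 44.6 (37.9 to 52.0) against 9.41 (7.34 to 11.9). Arg1 was also at 33.4 against 1.64 CPM in neutrophil-like and 30.7 against 2.19 CPM in B cell-like cells. In those classes it is possible free RNA, so free RNA is not excluded for Arg1 in monocyte-like cells. The size rule gave 25 genes higher and 12 lower of 9293 in monocyte-like cells, 27 of them possible free RNA. In B cell-like cells it gave 33 higher and 16 lower of 6994, 30 of them possible free RNA. Higher were Sorcs2 (45.5 against 9.31 CPM), Lmo7 (42.0 against 10.4) and Agbl1 (188 against 72.9). Lower were Rgcc (11.9 against 40.5), the spermidine synthase gene Srm (4.55 against 23) and the ribosomal pseudogene Rps18-ps6 (6.25 against 25.2). Reads of a pseudogene may be shared with its parent gene. Unfolded protein response genes had a median of -0.35 in B cell-like cells and MHC class I genes -0.31 (percentile 0 for both).

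Set beside the knockdown, the SE to CT ratios went the opposite way across genes in hepatocyte-like cells. The correlation of the log2 ratios across 8448 genes was -0.61 by Pearson and -0.59 by Spearman, and 7 of 92 genes called in the knockdown had the same sign. The share of the class in cluster 14 also went opposite ways, being higher in SE than in CT (436 of 501 and 81 of 178 cells) and lower in each shSEPP1 library than in each shNC library. Within that cluster alone the correlation was -0.19 by Pearson and -0.17 by Spearman across 5398 genes, and 12 of 38 called genes had the same sign. Neutrophil-like cells had -0.21 and -0.11, with 145 of 375 called genes of the same sign, and macrophage-like cells 0.07 and 0.04, with 8 of 26. In the largest macrophage cluster Pearson's value turned to -0.12. In monocyte-like cells the values were -0.02 and 0.03, with 3 of 6, in T cell-like cells 0.11 and 0.15, and in B cell-like cells 0.07 and 0.13. Genes are not independent replicates, and no library is shared between the comparisons.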

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

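The tests of the interferon, matrix and granule genes, among them those within the 4 libraries, within the largest cluster and without a neutrophil cluster, were chosen after these patterns were seen, with their bounds written before the tested values were computed, except that the test of free RNA for the granule genes was set after the levels were seen, in place of one whose bound was out of reach at these levels. The counts of genes over other splits of the libraries were chosen after their values were seen, and the count of gene lists over them before. The rule that a value must clear its bound by the spread of the genes was set after the values and can only weaken a statement.

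Cells left without a name were more frequent in shSEPP1, at a mean of 3.11% of kept cells against 1.87% in shNC, with each shSEPP1 library above each shNC library. Cluster 26, with 582 cells of neutrophil genes led by hemoglobin genes such as Hbb-bs, took 1.11% in shSEPP1 and 0.450% in shNC. Cluster 21.5, with 15 cells holding cholangiocyte and hepatocyte markers together, took 0.0358% and 0.00684%. Cd72 passed the threshold in monocyte-like cells alone among the 6 classes, but its shSEPP1 libraries all lay above the shNC libraries in T cell-like cells and all below them in macrophage-like, monocyte-like and hepatocyte-like cells. Its log2 fold change was 0.28 in T cell-like cells, above that in macrophage-like cells (-0.38) by 0.655, in monocyte-like cells (-1.81) by 2.09 and in hepatocyte-like cells (-0.70) by 0.978; the differences were not tested.

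Interferon response genes were lower in shSEPP1 neutrophil-like cells (median log2 fold change -1.60 over 22 genes). Within the 4 libraries with fewer barcodes the median was -1.48 (SD over genes 0.690), with 22 of 22 genes lower. The replicate 1 libraries left out there come from both groups, so a shift shared by them could not produce the difference in the first place. The value shows only that the fall does not rest on the replicate 1 libraries. A smaller share of an interferon-high cluster of neutrophils may account for part: within the largest cluster alone the median was -0.53 (SD 0.513, 15 of 17 genes lower), too close to the bound of -0.5 to decide. An effect of the knockdown stays open beside it, as a hypothesis.

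Extracellular matrix genes were higher in shSEPP1 in 5 immune classes (medians 1.19 to 1.55). Free RNA from stellate/fibroblast-like cells, whose share was 2.51-fold higher in shSEPP1, may be the source. Genes outside the list that these cells lead had medians of 0.533 in neutrophil-like, 0.589 in macrophage-like, 0.398 in T cell-like, 0.311 in monocyte-like and 0.233 in B cell-like cells, higher in each class but below the matrix genes. The bound set in advance for free RNA, 0.5 in each class, was passed in neutrophil-like and macrophage-like cells and missed in T cell-like, monocyte-like and B cell-like cells, and the value in B cell-like cells alone lay under the bound against it, so free RNA and a change in the immune cells themselves cannot be told apart.

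The granule genes Camp, Ngp, Ltf and Chil3 were higher in shSEPP1 neutrophil-like cells. Cluster 8 held more cells in each shSEPP1 library than in any shNC library. Cluster 43, led by Ngp, Camp and Ltf, held 0, 2 and 3 cells in shNC and 30, 51 and 13 in shSEPP1. Without it the median log2 ratio of the 4 genes went from 3.24 to 1.55 (SD 1.14), the larger cluster 8 still included. Camp was then at 1.20, Ngp at 1.90, Ltf at 0.31 and Chil3 at 3.01. Free RNA from immature neutrophils is argued against as the cause of the rise over the class: T cell-like and B cell-like cells of shSEPP1 held means of 1.35 to 8.86 CPM of the 4 genes against 179 to 540 CPM in neutrophil-like cells, and the excess over the highest shNC library was 4.03 to 39.0 times the upper 95% Poisson bound of the T and B cell levels, scaled by UMIs per cell, for each gene in each shSEPP1 library. Within the largest cluster the median log2 fold change was 2.77 (SD 2.15) and this ratio only -0.832 to 2.43, so free RNA stays open for the smaller rise there. In shSEPP1 replicates 1, 5 and 6 cluster 43 held 88.6%, 97.3% and 68.1% of the class's Camp UMIs. It held 68.5%, 83.1% and 40.0% of Ngp, 71.4%, 86.4% and 44.8% of Ltf and 10.6%, 21.5% and 5.78% of Chil3. Much of the rise of Camp, Ngp and Ltf thus lay in these few cells. Without them free RNA was not tested and stays open. For Chil3 and the rise left then, more immature neutrophils and a change within mature cells also stay open.

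Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. Neutrophil-like cells had 391 genes in the real split and at most 2 in another, macrophage-like cells 28 and 0, hepatocyte-like cells 112 and 3, monocyte-like cells 6 and 9, T cell-like cells 0 and 154, and B cell-like cells 0 and 3. As many genes as in the real split were found in 1 split for neutrophil-like, macrophage-like and hepatocyte-like cells, 2 for monocyte-like cells, and 10 for T cell-like and B cell-like cells. The 154 genes in T cell-like cells came from setting shNC replicate 1 with shSEPP1 replicates 1 and 5 against the rest. This points to a structure of the samples other than the groups. That split, with both replicate 1 libraries on one side, also gave the 9 genes in monocyte-like cells. Other splits passed 24 to 60 gene lists, this one 60, against 61 in the real split. With a term for the library set, edgeR called 0 genes in T cell-like and 323 in monocyte-like cells.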

How the results depend on the processing

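The settings within 4 libraries, within the largest cluster, at a mean CPM of 50 and with sub-clusters named by their own markers were chosen after the data were seen. No paired analysis was possible because the replicate numbers 1, 2 and 3 of shNC and 1, 5 and 6 of shSEPP1 share fewer than 2 numbers, and the shared 1 is itself uncertain in both groups. Over 185 results and 2129 alternatives, 1606 stayed the same, 318 kept their direction but lost the threshold, 5 passed it newly, 179 moved and 21 reversed. Leaving out a library gave 588 of 749 the same, 123 lost, 28 moved and 10 reversed. For tested genes and lists, the same meant an unchanged direction and side of the threshold. It meant direction alone for shares of shSEPP1 and shNC, and a count within 1.5-fold for counts. For SE and CT shares and genes, and for correlations, it meant a value within the range set by 95% intervals. The cause was not tested except where the setting itself uses fewer genes, cells or libraries. In the counts simulated for these libraries, 2-fold changes were recovered for 20.9% of genes in hepatocyte-like cells, the lowest share of the 6 classes.

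Counts of called genes in neutrophil-like, macrophage-like, T cell-like, monocyte-like, hepatocyte-like and B cell-like cells were 391, 28, 0, 6, 112 and 0. DESeq2 gave 843, 437, 4, 134, 242 and 5, no filter on low counts 1105, 216, 293, 454, 815 and 121, and within the 4 libraries 128, 33, 13, 245, 0 and 6. A mean CPM of at least 20 gave 191, 6, 3 and 33 in neutrophil-like, macrophage-like, monocyte-like and hepatocyte-like cells. The library set term gave 1100, 437, 323 and 31 in neutrophil-like, macrophage-like, monocyte-like and B cell-like cells. The largest cluster alone gave 8, 37 and 2 in macrophage-like, monocyte-like and hepatocyte-like cells. In monocyte-like cells relative log expression factors gave 13, resolution 0.5 gave 55, resolution 2 gave 0, equal cell numbers 1, free RNA genes left out 13 and doublets kept 14. In hepatocyte-like cells doublets kept gave 2, the stricter cell filter 72 and equal cell numbers 22; in B cell-like cells resolution 2 and free RNA genes left out gave 1 each. Leaving out 1 library gave 0 to 517 in neutrophil-like, 0 to 130 in macrophage-like, 0 to 86 in T cell-like, 0 to 116 in monocyte-like, 4 to 730 in hepatocyte-like and 0 to 8 in B cell-like cells.

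Selenop in hepatocyte-like cells was at -1.53 with doublets kept (edgeR adjusted p = 0.0501), -1.65 within the 4 libraries (0.237), -3.68 in the largest cluster (6.4e-05) and -1.79 to -1.55 leaving out 1 library; the adjusted p of these lay above 0.05 also without shNC replicate 1 (0.0782) and shSEPP1 replicate 1 (0.061). Selenop turned direction in T cell-like cells in the largest cluster (-0.081) and over -0.10 to 0.64 leaving out 1 library, and in B cell-like cells with equal cell numbers (0.018). In the largest neutrophil cluster Ltf turned to -0.13 and Ifit1 to 0.034. Of 181 gene lists tested 61 passed, 0 with an estimated correlation, 3 by fry and 64 by its mixed form. Leaving out 1 library passed 10 to 17 others. With free RNA genes left out 40 of 124 lists tested passed, 35 of them among the 61, of which 39 were still tested; there the granule list in macrophage-like cells turned to -0.037.

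The log2 ratio of the neutrophil-like share, -0.01, was 0.035 under the stricter cell filter, 0.0075 at resolution 0.5, 0.0018 at resolution 2 and -0.11 to 0.046 leaving out 1 library; that of monocyte-like cells spanned -0.032 to 0.42 and that of gamma-delta/IL17 T-like cells -0.32 to 0.44. At the lower sub-cluster resolution 4 subclasses separated the groups and CD4 T-like cells turned to 0.22; leaving out 1 library 2 to 4 did. Lipid-associated macrophage-like cells turned to -0.020 when named by sub-cluster markers alone.

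For SE and CT, the size rule gave 48, 126, 108, 37, 467 and 49 genes in the 6 classes. CPM + 1 gave 210, 455, 189, 69, 1016 and 105, and CPM + 50 gave 21, 31, 20, 6, 97 and 22. At least 200 UMIs gave 59, 22, 254 and 16 in T cell-like, monocyte-like, hepatocyte-like and B cell-like cells, free RNA genes left out 12, 10 and 20 in neutrophil-like, monocyte-like and B cell-like cells, the size alone 75 in B cell-like cells, and doublets kept and resolution 2 gave 211 and 931 in hepatocyte-like cells. At a mean CPM of at least 50 the correlations with the knockdown were -0.28 in neutrophil-like, 0.14 in macrophage-like, 0.19 in T cell-like, -0.66 in hepatocyte-like and 0.13 in B cell-like cells. In the largest cluster alone they were -0.24 in neutrophil-like, -0.12 in macrophage-like, 0.047 in T cell-like, -0.077 in monocyte-like and -0.19 in hepatocyte-like cells.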

Other observations

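These values come from the lists fixed in advance, and no further test was chosen for them.

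Further gene lists passed camera with its preset correlation between shSEPP1 and shNC. Other splits of the 6 libraries passed 24 to 60 lists by that test, against 61 in the real split. A passing list thus does not by itself set the groups apart. Glycolysis and hypoxia genes were higher in macrophage-like cells (median log2 fold change 0.33 over 18 genes, 3 higher adjusted over the list alone, camera adjusted p = 1.4e-06; adjusted p = 0.302 with an estimated correlation). They were higher in neutrophil-like cells too (0.36 over 17 genes, 1 higher and 1 lower, 0.00461; adjusted p = 0.638 with an estimated correlation). Oncofetal and progenitor genes were higher in neutrophil-like cells (0.46 over 11 genes, 0.00507; adjusted p = 0.31 with an estimated correlation). There Gpc3, a surface proteoglycan of liver tumours, rose from 56.2 ± 8.69 to 148 ± 22.6 CPM (SD, n = 3; edgeR adjusted p = 0.0144). The list was higher in macrophage-like cells (0.69 over 9 genes, 0.00012; adjusted p = 0.31 with an estimated correlation) and B cell-like cells (0.21 over 7 genes, 0.0068; adjusted p = 0.354 with an estimated correlation). In these classes 7, 6 and 3 of the members were possible free RNA. Dissociation stress genes were higher in T cell-like cells (0.36 over 16 genes, 4 higher adjusted over the list alone, 4.5e-09; adjusted p = 0.302 with an estimated correlation). In macrophage-like cells they had a median of 0.49 (16 genes, none called, 0.00394; adjusted p = 0.653 with an estimated correlation), lost without shNC replicate 1 or shSEPP1 replicate 6 (0.575). The median mitochondrial share was 2.86%, 3.65% and 3.56% in T cell-like cells of shNC and 2.89%, 3.96% and 4.18% of shSEPP1, and 2.90%, 3.76% and 3.58% and 2.94%, 4.24% and 4.26% in macrophage-like cells.

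Cholesterol synthesis genes were lower in B cell-like cells (-0.48 over 9 genes, none called, camera adjusted p = 0.000104; adjusted p = 0.302 with an estimated correlation). In T cell-like cells they had a median of -0.29 (12 genes, 0.0146; adjusted p = 0.421 with an estimated correlation), lost without shNC replicate 2 (0.122). Oxidative phosphorylation genes were lower in T cell-like cells (-0.29 over 18 genes, 0.000125; adjusted p = 0.467 with an estimated correlation). MHC class II genes were lower in hepatocyte-like cells (-0.72 over 6 genes, all possible free RNA, 0.000125; adjusted p = 0.239 with an estimated correlation) and T cell-like cells (-0.61 over 6 genes, all possible free RNA, 0.0205; adjusted p = 0.582 with an estimated correlation). The hepatocyte-like result was lost with possible doublets kept (0.517). Lists of T cell genes were lower in cells that are not T cells: exhaustion and checkpoint genes in neutrophil-like cells (-0.50 over 8 genes, 4 lower adjusted over the list alone, 0.000299; adjusted p = 0.302 with an estimated correlation). Cytotoxic effector genes were lower in neutrophil-like, macrophage-like and monocyte-like cells (-0.63, -0.52 and -0.65; camera adjusted p = 0.0197, 0.0416 and 0.0443; adjusted p = 0.302, 0.316 and 0.582 with an estimated correlation). Inflammatory cytokine genes had medians of 0.20 in macrophage-like and -0.29 in hepatocyte-like cells (0.0155 and 0.0401; adjusted p = 0.637 and 0.519 with an estimated correlation). Chemokines had a median of 0.15 in macrophage-like cells (0.0496; adjusted p = 0.542 with an estimated correlation), and neutrophil granule genes 0.15 in T cell-like cells (0.00428; adjusted p = 0.316 with an estimated correlation).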
